A study of Mus musculus with 2 samples.

How the data were processed

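The data are droplet-based single-cell RNA counts from CD45-positive cells sorted out of GL261 tumours, a mouse glioma line grown in the brains of C57BL/6 mice. 1 library came from mice given PBS and 1 from mice given ibudilast by gavage at 20 mg/kg, 5 times per week for 2 weeks. The label of the control library calls it untreated while its protocol names PBS, and it is called PBS here. The number of mice behind each library is not given in the sources used here.

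The deposited values are raw UMI counts per gene and cell barcode. They were made by the authors with Cell Ranger 6.1.1, per the file headers, and on the mouse genome build mm10, per the submitters' processing notes. The deposited tables hold barcodes already called as cells: the lowest total was 501 UMIs in the PBS library and 500 in the ibudilast library. Empty droplets were not used here, so free RNA in the droplets was judged only from genes found outside the cell classes that express them. Both libraries list the same 31253 genes, of which 20003 and 20093 had a UMI. 31107 of the gene identifiers matched the reference names, 30203 of them with the same symbol. Gene positions are those of GENCODE M21 on mm10 (GRCm38).

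Cells were kept with at least 300 genes, at least 500 UMIs and under 10% of UMIs on mitochondrial genes. This left 8155 of 8968 PBS barcodes and 7079 of 8483 ibudilast barcodes. Scrublet, run in scanpy 1.11.5 on each library, set an automatic threshold that marked 2 cells and 0 cells. As fixed for that case, the 6% of cells with the highest doublet scores were left out of each library, 489 and 425 cells. The kept 7666 PBS and 6654 ibudilast cells had median UMI counts of 11669 and 7829 and median gene counts of 2924 and 2285.

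Counts of both libraries were log-normalised and clustered together without batch correction, on 2000 variable genes, 30 principal components and 15 neighbours, with Leiden clustering at resolution 1. The 28 clusters were named from fixed marker lists. A name needed at least 3 markers at 20 CPM or more and at 1.5 times or more the mean of the other clusters. A cluster stayed unnamed when its 10 leading genes held more markers of another class than of its own, or when its cells were shallow and none of its own markers led it. Haemoglobin genes, found in every cluster, named none. Most of their UMIs lay in 4 PBS and 14 ibudilast cells with at least 20 of them, a limit set after the data were seen. Unnamed cluster 20 held 1 and 2 of these cells. 25 clusters were named in 14 classes and 3 stayed unnamed: cluster 0, cluster 20 and cluster 21. The way marker scores are turned into names was revised after a first naming had been seen. The markers themselves were not changed. T-cell-like cells were clustered again on their own, without T cell receptor variable genes, into 12 subclusters, of which 7 stayed unnamed.

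Within each class, counts were summed per library and divided by the summed UMIs of that class and scaled to CPM. Sums have exact Poisson 95% intervals, shares exact Clopper-Pearson 95% binomial intervals, and ratios of ibudilast to PBS exact conditional binomial 95% intervals. All of these cover counting error only. The intervals of UMI sums and of their ratios leave out the spread between cells, so they are too narrow where few cells carry most UMIs. With 1 library per group there was no test, and the ratios compare these libraries, not the treatments. Over 21 fixed gene lists, the median log2 ratio of members with at least 20 UMIs was computed after adding 0.5 UMIs to each sum. Its percentile among 10000 random lists of the same size, matched on expression in 10 levels, describes these libraries. An interval of each median came from 1000 Poisson redraws of the counts. Members above 1.25-fold and under 0.8-fold were counted by the ratio alone. Cells with at least 2 UMIs over the cycling markers were counted after each cell was thinned to 1000 UMIs, with shallower cells left out. Gene ratios in thinned cells rest on 1000 UMIs per cell and have no interval, so they are imprecise for genes of low level.

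Genes named from a class follow a fixed rule. Classes with at least 300 kept cells in each library were ranked, 6 in all. Genes needed at least 100 UMIs, and a UMI in at least 10% of the cells of the library with the higher level. They were ranked by the interval bound nearest to 1. The 6 highest and 6 lowest with that bound beyond 1.25-fold were named in the 4 largest classes, and the 3 highest and 3 lowest in the others. Mitochondrial, ribosomal protein, haemoglobin, antigen receptor, sex-linked check genes and unnamed gene models were left out. Up to 4 members of each list, and Mif, Cd74, Pde4b and Pde4d in every class, could be named as well. 1 gene named by the ranking is not reported here. Genes given outside this rule are called chosen after their values were seen.

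The filters, comparisons, gene lists, markers and the rule for named genes were set before the data were examined, and so were alternatives for the cell filter, doublets, clustering, scaling, thinning and low counts. The scalings used TMM factors of edgeR 4.0.16 and size factors of DESeq2 1.42.0 in R 4.3.3. Further alternatives were chosen after the data were seen. They leave out the mixed T and NK clusters, those with over 50% of the C1qa level of macrophage-like cells. They count cluster 0 with the macrophage-like class, weight the clusters of a class alike in both libraries, count cycling clusters with their second-best class, or cluster and name cells without the 45 ranked genes. The 21 list medians the text leads with were picked from 272, over 13 cell groups, after their values were seen. Of the 272, 64 lay above the 97.5 percentile of random lists and 70 below the 2.5 percentile, 60 and 66 of them with an interval that excludes 0. A list median is treated as standing apart only when its interval excludes 0 and its percentile lies outside these limits, a rule set after a first run of the alternatives.

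The ratio intervals were tested on simulated data for the macrophage-like class, with 9618 genes and known folds. 95.7% of intervals held the true fold. The bound lay beyond 1.25-fold for 84% of genes lowered to 0.5-fold, 54% lowered to 0.67-fold, 62% raised 1.5-fold, 98% raised 2-fold and 0.0212% of unchanged genes. Of unchanged lists of 12 genes, 4% lay outside the percentile limits. All lists raised 1.5-fold lay above the upper limit. The simulation holds counting error alone, so it says nothing of differences between cells or between mice.

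Clec7a and Mx1, members of fixed lists, and the markers Tcrg-C1 and Tcrg-C2 were not analysed here. Both libraries came from female mice by their counts: Xist had 101602 and 69515 UMIs in kept cells, and 4 Y-linked genes had 0 UMIs, apart from 1 Uty UMI in the ibudilast library. 19 barcode sequences occurred in both libraries. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and igraph 0.11.9.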

Results

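The series profiled immune cells of GL261 gliomas by single-cell RNA sequencing. CD45, the surface protein used for the sort, marks cells of blood origin and microglia. 1 library came from mice given PBS and 1 from mice given ibudilast, a small molecule that inhibits phosphodiesterases and the cytokine MIF. The PBS library held 8968 barcodes and 119113794 UMIs (median 11052.5 per barcode), and the ibudilast library 8483 barcodes and 82196922 UMIs (median 6809). After filtering, 7666 PBS and 6654 ibudilast cells remained. There were no replicates, so no difference reported here has a replicate check. Intervals are at 95% and cover counting error only, not the spread between cells or mice. Members of a gene list are called higher or lower when their ratio lies beyond 0.8-fold or its inverse.

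The first comparison asked how the makeup of the CD45-positive infiltrate differed with ibudilast. Macrophage-like cells made up 25.1% of the PBS library and 12.5% of the ibudilast library (ratio 0.500, interval 0.461 to 0.543). The clusters of that class went both ways as shares of kept cells. Clusters 2 and 3 had ratios of 0.390 and 0.225. Cluster 9 was at 3.61% and 5.00% (ratio 1.385, interval 1.18 to 1.63), and cluster 23 had a ratio of 1.22 (interval 0.894 to 1.67). NK-cell-like cells made up 4.16% and 8.88% (ratio 2.13, interval 1.86 to 2.45). T-cell-like cells were 14.4% and 19.1% (ratio 1.33, interval 1.22 to 1.44), and monocyte-like cells 15% and 21.6% (ratio 1.44, interval 1.33 to 1.56). Shares of dendritic cells were also higher in the ibudilast library: cDC2-like cells had a ratio of 1.36, cDC1-like cells of 1.44 and migratory dendritic-cell-like cells, which carry Ccr7 on their way to lymph nodes, of 1.62. With each library clustered on its own, no ibudilast cluster was named cDC2-like and the cDC1-like one held 508 cells, led by Xcr1 and Cd209a among others, so the cDC1-like ratio of 4.47 found there compares unlike classes. Microglia-like cells were 3.48% and 2.03% (ratio 0.583, interval 0.470 to 0.719). Mast-cell- or basophil-like cells were 1.10% and 0.586% (ratio 0.535, interval 0.356 to 0.791).

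Plasmacytoid dendritic-cell-like cells were 1.27% and 1.26%, and neutrophil-like cells 0.939% and 0.827%. B-lineage-like cells were 1.96% and 1.56% (ratio 0.799, interval 0.616 to 1.03). Clusters of cycling cells were 5.97% and 4.97% (ratio 0.833), a direction that turned to 1.18 with each library clustered on its own. Non-immune cells, which the CD45 sort should remove and which sat mostly in a cluster led by genes such as Apod and Mag, were 0.587% and 2.84% (ratio 4.84, interval 3.48 to 6.86). That ratio was 1.84 with a stricter cell filter, 2.95 at resolution 0.5 and 2.51 with the libraries clustered apart.

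Unnamed clusters held 17.1% of PBS and 11% of ibudilast cells. Most were in cluster 0, which scored closest to macrophages and held 14.9% and 7.78% of cells. With cluster 0 counted in, the macrophage-like share was 40.0% and 20.3% (ratio 0.509, interval 0.477 to 0.542). Shares sum to a whole, so they were also taken among cells outside the macrophage-like class and cluster 0. On that base T-cell-like cells were 24.1% and 24.0% (ratio 0.999) and monocyte-like cells had a ratio of 1.09. NK-cell-like cells were still 6.93% and 11.1% (ratio 1.61), and microglia-like cells 5.80% and 2.55% (ratio 0.439). On the same base the ratios of dendritic cells had intervals that held 1: 1.02 for cDC2-like (0.895 to 1.17), 1.09 for cDC1-like (0.837 to 1.41) and 1.22 for migratory dendritic-cell-like cells (0.995 to 1.49). The B-lineage-like ratio was 0.602 there (0.464 to 0.778). Genes that lead some clusters, such as Lpl, Gdf15, Ccl17 and Gzmc, differed between the libraries. Clustered and named without the 45 genes of the ranking, the shares had ratios of 0.583 for macrophage-like, 2.17 for NK-cell-like and 1.37 for cDC2-like cells. The sort sets which cells entered, kept cells differed in depth (medians of 11669 and 7829 UMIs), and 8.93% of PBS but 15.6% of ibudilast barcodes were lost to the mitochondrial limit. The libraries also differed in haemoglobin RNA, at 7.43 and 72.5 CPM over kept cells with fewer than 20 haemoglobin UMIs.

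**Figure D1:**
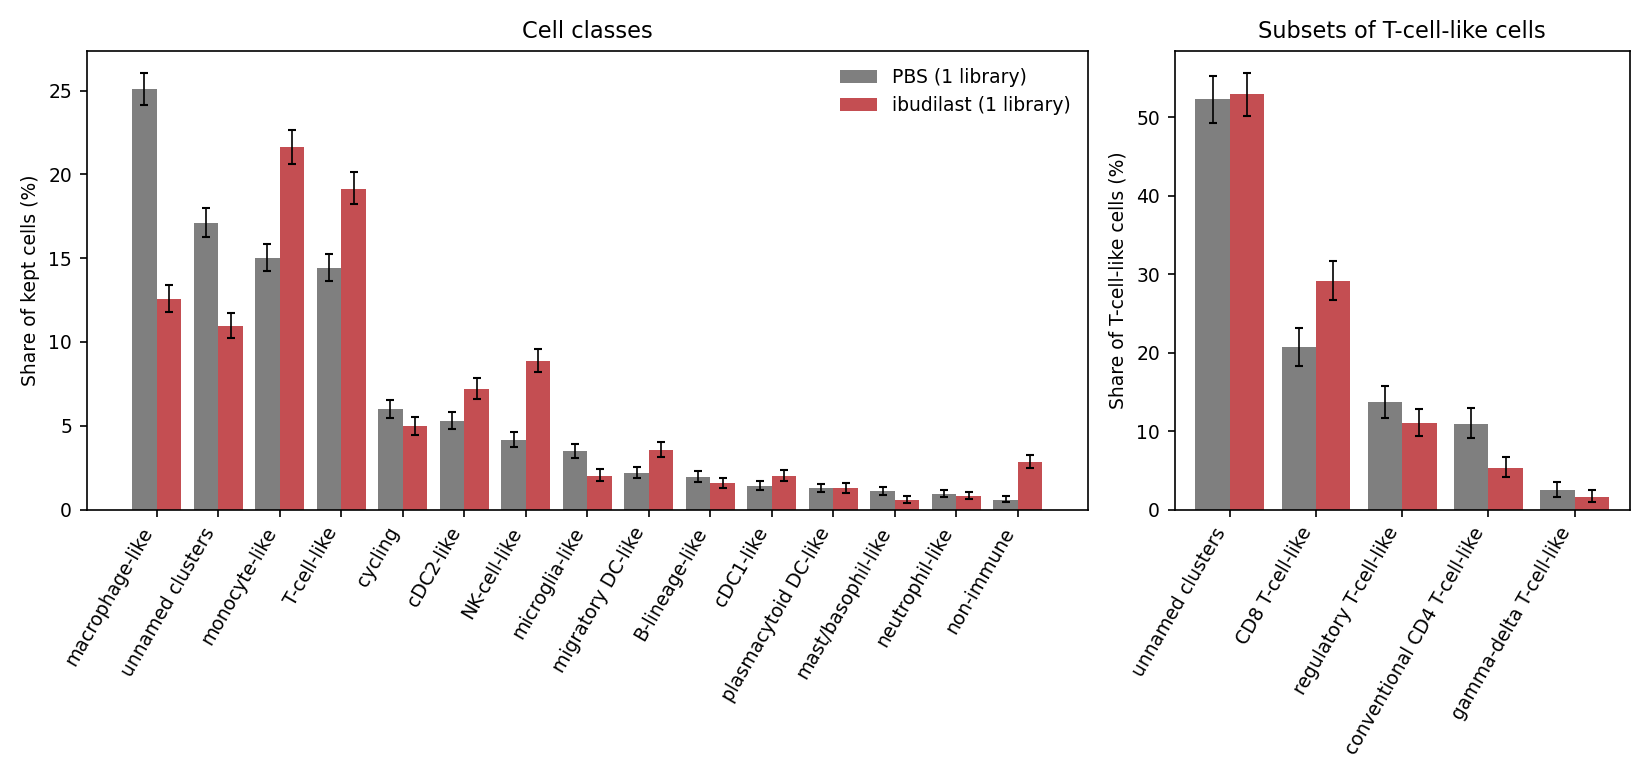
Bars give the share of kept cells in each cell class (left, %) and the share of T-cell-like cells in each subset (right, %) in the PBS and ibudilast libraries, 1 library each, with exact 95% binomial intervals for counting error. Macrophage-like cells stand at 25.1% and 12.5%, NK-cell-like cells at 4.16% and 8.88%.

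Among T-cell-like cells, CD8 T-cell-like cells made up 20.7% in the PBS and 29.1% in the ibudilast library (ratio 1.41, interval 1.19 to 1.67). Conventional CD4 T-cell-like cells made up 10.9% and 5.34% (ratio 0.488, interval 0.357 to 0.663). Regulatory T-cell-like cells were 13.6% and 11% (ratio 0.806, interval 0.636 to 1.02), with a ratio of 1.07 at resolution 2. Gamma-delta T-cell-like cells were 2.44% and 1.65% (ratio 0.676, interval 0.363 to 1.24). Subclusters with no name held 52.3% and 52.9%. After thinning to 1000 UMIs, 5.84% of PBS and 5.66% of ibudilast cells had at least 2 UMIs of the cycling markers (ratio 0.968, interval 0.840 to 1.12). Without thinning these shares were 25.9% and 22.2%, and thinning left out 165 and 341 shallow cells. Within NK-cell-like cells, which leave out the cycling clusters, the thinned shares were 2.83% and 1.03% (ratio 0.364, interval 0.107 to 1.15). The unthinned shares there were 25.1% and 17.1%, with 1 and 9 shallow cells left out, and median depths of 9519 and 5970 UMIs. For comparison, the thinned shares were 0.351% and 0.210% in monocyte-like cells (median depths of 7291 and 6117 UMIs) and 1.47% and 1.92%, from 1 cell each, in neutrophil-like cells, which do not divide.

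The next comparisons asked which genes differed within a class. Macrophage-like cells of the ibudilast library carried more RNA of Chil3 (ratio 3.83, interval 3.43 to 4.28), Ly6c2 (3.20, 3.09 to 3.31) and Gdf15 (3.40, 3.14 to 3.68). Chil3 encodes a chitinase-like protein and Ly6c2 the Ly6C antigen of monocytes, and Gdf15 is a stress-induced cytokine. Cd24a (3.90), Apod (3.96) and Ahnak (3.27) were the other highest genes. The lowest were Plxdc2 (0.204), Mgl2 (0.259, interval 0.227 to 0.293), H2-M2 (0.284), Adrb1 (0.335), Lpl (0.377) and Slc13a3 (0.386). Mgl2 encodes the lectin CD301b and Lpl lipoprotein lipase. The class held different clusters in the libraries. Cluster 3, led by Lpl, H2-M2, Mmp12, Mrc1 and Arg1, held 41.5% of it in the PBS and 18.7% in the ibudilast library, and cluster 9, led by Gdf15, 14.4% and 39.9%. Mgl2 is among the genes that lead cluster 0 and cluster 23. With the clusters weighted alike, the ratios were 1.59 for Chil3, 1.82 for Ly6c2, 1.56 for Gdf15, 1.76 for Cd24a and 2.03 for Ahnak. Adrb1 had a ratio of 0.571 with a stricter cell filter, 0.535 with doublets kept and 0.546 with cluster 0. Plxdc2 had 0.342 with each cell weighted alike, and Mgl2 had 0.167 in thinned cells. Other classes carried Chil3, Ly6c2, Cd24a, Apod, Ahnak and Plxdc2 at over 5 times the macrophage-like level.

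MHC class II genes were lower in macrophage-like cells of the ibudilast library. The median log2 ratio of 8 members was −0.39 (percentile 0 among random lists), and 7 were lower, among them Cd74 (0.687), H2-DMb1 (0.692), H2-Eb1 (0.763) and H2-Aa (0.768). The median was −0.22 with clusters weighted alike, −0.24 with doublets kept and −0.20 in cluster 0. Type I interferon response genes were higher, with a median of 0.34 (percentile 100) and 9 of 17 members higher, such as Ifit1 (1.63), Isg15 (1.57) and Ifit3 (1.48). The median was 0.22 with a stricter cell filter and 0.10 in cluster 0. Chemokine genes had a median of −0.27 (percentile 0.01), with 7 of 14 lower, such as Ccl9 (0.625) and Ccl12 (0.706), while Ccl5 was at 1.62. Pro-inflammatory cytokine and NF-kB target genes had a median of −0.19 (percentile 0.04), with Il1a at 0.604 and Ptgs2 at 0.682.

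The response genes of cAMP and CREB had a median of 0.23 in macrophage-like cells (percentile 99.81), with 7 of 16 members higher, such as Vps37b (1.75) and Nr4a1 (1.5). It was 0.05 with the stricter filter, 0.06 with clusters weighted alike, 0.07 with cluster 0 and 0.11 with doublets kept. Genes of dissociation stress had a median of 0.17 in the same cells (percentile 99.96), which was −0.05 with the stricter filter. Immunosuppressive macrophage genes went both ways: Thbs1 (2.74) and Fn1 (1.87) were higher and Mrc1 (0.489) lower. Their median of 0.14 (percentile 98.77) was −0.05 with the stricter filter, 0.04 with doublets kept or with cluster 0, and 0.08 with either other scaling. Among genes of disease-associated microglia the median was 0.26 (percentile 100), with Gpnmb at 2.81 and Fabp5 at 2.50, which lead cluster 9. It was 0.07 with clusters weighted alike, 0.15 with doublets kept and 0.16 with cluster 0. Markers of T and NK cells were higher in the same class: cytotoxic effector genes had a median of 0.90 (percentile 100), with Gzma at 2.74 and Nkg7 at 2.10.

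**Figure D2:**
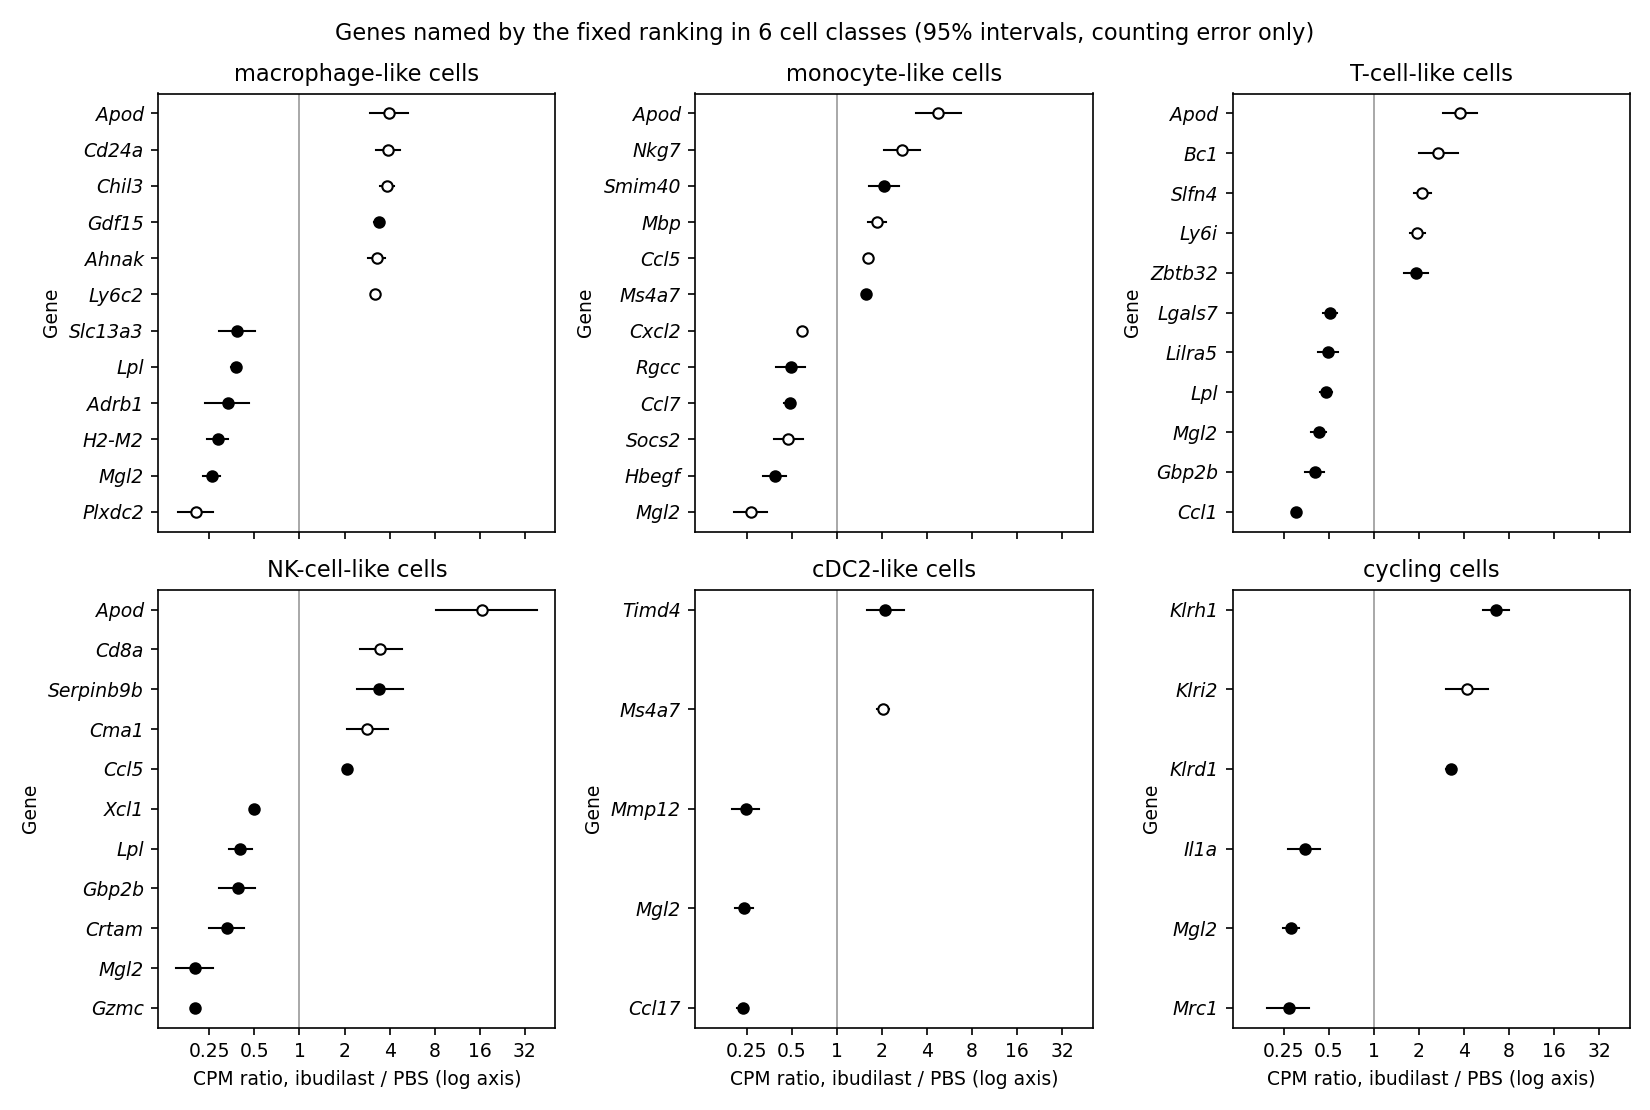
Points give the ratio of CPM in the ibudilast library to the PBS library (log axis) for genes that the fixed ranking named in 6 cell classes, with 95% intervals for counting error; open circles mark genes that another class carried at over 5 times the level. Mgl2 is among the lowest genes in all 6 classes, with ratios from 0.201 to 0.428. Filled circles include genes that another class carried at a higher level, such as Mgl2 and Lpl in T-cell-like and NK-cell-like cells.

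In monocyte-like cells the lowest genes were Mgl2 (0.267), Hbegf (0.387), Socs2 (0.477), Ccl7 (0.486, interval 0.447 to 0.528), Rgcc (0.493) and Cxcl2 (0.583, interval 0.562 to 0.605). Ccl7 attracts monocytes and Cxcl2 neutrophils. Both belong to the chemokine list, whose median was −0.21 (percentile 0; 5 of 14 lower, while Ccl5 was at 1.61). The highest genes were Apod (4.76), Nkg7 (2.71), Smim40 (2.07), Mbp (1.87), Ccl5 (1.61) and Ms4a7 (1.57, interval 1.49 to 1.65). Apod, Nkg7, Mbp, Ccl5, Cxcl2, Socs2 and Mgl2 were carried at over 5 times the level by another class, Nkg7 by NK-cell-like and Apod and Mbp by non-immune cells. The median over immunosuppressive macrophage genes was −0.21 (percentile 0.01), with Arg1, the gene of arginase, at 0.217, Mrc1 at 0.428, Chil3 at 0.624 and Fn1 at 0.628. It was −0.10 with doublets kept. Type I interferon response genes had a median of 0.13 (percentile 99.98), with Isg15 at 1.37 and Ifit3 at 1.19, and 1 of 17 members higher. In thinned cells, where few UMIs of these genes remain, Rgcc had a ratio of 0.274 and Mgl2 of 0.0941. With the stricter cell filter the interferon median was 0.22.

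In T-cell-like cells Ccl1, a chemokine of activated T cells, was at 271.7 CPM in the PBS and 82.5 CPM in the ibudilast library (ratio 0.304, interval 0.285 to 0.323). Its 4154 and 1338 UMIs came from 12.2% and 9.18% of the cells, so that interval, which leaves out the spread between cells, is too narrow. Gbp2b (0.402), Mgl2 (0.428), Lpl (0.479), Lilra5 (0.492) and Lgals7 (0.510) were the other lowest genes. Mgl2, Lpl, Lilra5 and Gbp2b were 2.99, 3.54, 2.16 and 2.25 times higher in cDC2-like, microglia-like, macrophage-like and cycling cells. Mixed cluster 5 was counted in the T-cell-like level. Ccl1 and Lgals7 lead cluster 11, which held 26.3% of the class in the PBS and 17.1% in the ibudilast library, and cluster 7, led by Cd8a, Klrd1 and Cxcr6 among others, held 22.9% and 32.8%. Among the highest were Apod (3.76), Bc1 (2.68), Slfn4 (2.10), Ly6i (1.95) and Zbtb32 (1.90, interval 1.58 to 2.30). Another class carried Apod, Bc1, Slfn4 and Ly6i at over 5 times the level: non-immune cells Apod and Bc1, neutrophil-like cells Slfn4 and monocyte-like cells Ly6i. Glycolysis and hypoxia genes were lower (median −0.30, percentile 0), with 9 of 18 members lower, such as Vegfa (0.615), Bnip3 (0.634) and Ero1l (0.666). In CD8 T-cell-like cells alone the median was −0.09 (percentile 3.08, interval −0.16 to 0.04). In regulatory T-cell-like cells it was −0.27 (percentile 0.185, interval −0.36 to −0.18). Vegfa and Bnip3 are among the genes that lead T subcluster 6, beside the macrophage genes Mmp12, Arg1 and Pf4. That subcluster held 99 of the 1107 T-cell-like cells of the PBS and 66 of the 1274 of the ibudilast library. Cytotoxic effector genes had a median of 0.23 (percentile 100), with Klrd1 at 1.55 and Prf1 at 1.45. It was −0.003 with clusters weighted alike and −0.06 in CD8 T-cell-like cells alone. In regulatory T-cell-like cells it was 0.59 (percentile 100, interval 0.37 to 0.88), with 10 of 14 members higher and 0 lower. The same list was at 1.04 in B-lineage-like, 0.96 in cDC1-like and 0.75 in monocyte-like cells, and stood above random lists in 11 of 13 groups. Free RNA of killer cells therefore stays open for the regulatory T-cell-like value. Exhaustion and checkpoint genes had a median of 0.16 (percentile 100), with Cxcr6 and Cd160 at 1.28 each. It was 0.10 with clusters weighted alike and 0.04 (percentile 57.5, interval −0.07 to 0.16) in CD8 T-cell-like cells. In regulatory T-cell-like cells it was 0.20 (percentile 99.13, interval 0.10 to 0.32). Type I interferon genes had a median of 0.17 (percentile 100) over the class, but of −0.05 (percentile 8.84) in CD8 T-cell-like and −0.09 (percentile 15.1) in regulatory T-cell-like cells.

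Part of the T-cell-like and NK-cell-like classes also carried macrophage RNA. In clusters 5 and 15 the C1qa level was over 50% of that of macrophage-like cells, and these clusters held 6.82% of PBS and 9.86% of ibudilast cells. Haemoglobin RNA, which belongs to red cells, also differed between the libraries. Without the 4 PBS and 14 ibudilast cells that had at least 20 haemoglobin UMIs, it was at 7.43 and 72.5 CPM over all kept cells. It was at 7.59 and 60.8 CPM in T-cell-like, 13.2 and 78.0 in NK-cell-like and 6.1 and 73.9 in macrophage-like cells. Without clusters 5 and 15 the T-cell-like ratio of shares was 1.37 and the NK-cell-like ratio 2.28. In the T-cell-like class the ratios without them were 4.58 for Bc1, 0.280 for Lilra5, 0.293 for Lpl and 0.201 for Mgl2. The type I interferon median was then 0.09 and, with doublets kept, 0.25.

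NK-cell-like cells of the ibudilast library had less Gzmc, a granzyme of strongly activated killer cells (1580 and 315.6 CPM, ratio 0.20, interval 0.189 to 0.211), and less Xcl1, the chemokine that draws cDC1 (ratio 0.496, interval 0.479 to 0.512). Both lead cluster 8, which held 69.0% of the class in the PBS and 71.4% in the ibudilast library. Crtam (0.327), an activation-induced adhesion receptor, Mgl2 (0.201), Gbp2b (0.386) and Lpl (0.402) were also lowest. Mgl2, Lpl and Gbp2b were 4.03, 3.75 and 2.45 times higher in cDC2-like, microglia-like and cycling cells, with mixed cluster 15 counted in the NK-cell-like level. In the PBS library Mgl2 was at 56.9 CPM in this class, but at 16.5 CPM in T and NK cells outside the mixed clusters. Ccl5 was at 2789 and 5757 CPM (ratio 2.06, interval 2.02 to 2.11), beside Cma1 (2.84), Serpinb9b (3.41), Cd8a (3.48) and Apod (16.5, from 8 and 187 UMIs). Cma1 was over 5 times higher in mast-cell-like, Cd8a in T-cell-like and Apod in non-immune cells. Cytotoxic effector genes had a median of 0.33 (percentile 100; 8 of 16 higher), with Ifng at 1.90 and Gzma at 1.70, while Cst7 was at 0.640. Cell cycle genes were lower (median −0.44, percentile 0), with 9 of 14 members lower, such as Tyms at 0.568. So were glycolysis and hypoxia genes (median −0.35, percentile 0), with 10 of 17 lower, such as Ero1l at 0.533. The cycling clusters are outside this class, so the cell cycle median leaves out their cells. Among them, cluster 16 held 1.40% of PBS and 2.28% of ibudilast kept cells, and NK-cell-like cells within it were not counted.

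The response genes of cAMP and CREB had a median of 0.33 in NK-cell-like cells (percentile 100), with 9 of 17 members higher, such as Nr4a1 (1.36) and Tsc22d3 (1.33). Genes of dissociation stress, which share Fos and Dusp1 with that list, had a median of 0.30 (percentile 100), with Egr1 at 1.42. Type I interferon genes had a median of 0.28 (percentile 100), with Ifit1 at 1.58, which was 0.16 with the stricter filter. Without the mixed cluster, Gbp2b had a ratio of 0.174, Mgl2 of 0.304 and Apod of 35.1. Apod had 36.5 with the stricter filter, 35.5 with each cell weighted alike and 3.54 with doublets kept. In thinned cells Serpinb9b had 1.80 and Cma1 1.86, and with each cell weighted alike Serpinb9b had 1.93.

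In cDC2-like cells Ccl17, a chemokine for CCR4-bearing T cells, was at 532.1 CPM in the PBS and 125.4 CPM in the ibudilast library (ratio 0.236, interval 0.217 to 0.255). Mgl2 was at 196.0 and 47.3 CPM (ratio 0.241, interval 0.211 to 0.275), and Mmp12, a macrophage elastase, had a ratio of 0.247. Ccl17 leads the cDC2-like cluster and both Ccl17 and Mgl2 are among its markers. Timd4 (2.11) and Ms4a7 (2.04) were among the highest, and Ms4a7, over 5 times higher in macrophage-like cells, had a ratio of 1.18 with doublets kept. Dendritic cell maturation genes went both ways, with Ccl22 at 0.504, Ccr7 at 0.735 and Cd86 at 1.24. Their median of −0.23 (percentile 0) was 0.09 with the stricter filter and 0.06 with doublets kept. Immunosuppressive macrophage genes had a median of −0.35 (percentile 0; 6 of 12 lower), with Thbs1 at 0.304, Fn1 at 0.553 and Ccl8 at 2.99. Type I interferon genes had a median of 0.21 (percentile 100; 5 of 17 higher), with Isg15 at 1.39. In thinned cells Timd4 had a ratio of 3.23 and Mmp12 of 0.136.

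In the cycling clusters, genes of killer lectin-like receptors were higher: Klrh1 (6.51), Klri2 (4.17) and Klrd1 (3.29, interval 3.05 to 3.54). Mrc1 (0.270), Mgl2 (0.280) and Il1a (0.345), genes of myeloid cells, were lowest. MHC class II genes had a median of −0.61 (percentile 0; 8 of 8 lower, such as H2-DMb1 at 0.626). These clusters differed in makeup: cluster 10, nearest to macrophages, held 76.6% of them in the PBS and 54.1% in the ibudilast library, and cluster 16, nearest to T cells, 23.4% and 45.9%. With both weighted alike, the ratios were 3.32 for Klrh1, 2.36 for Klri2 and 1.75 for Klrd1, and the MHC class II median was −0.25. Mrc1 had a ratio of 0.719 and Mgl2 of 0.183 in thinned cells, and Il1a of 0.528 with each cell weighted alike.

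The targets of ibudilast formed the last comparison. Cd74, the invariant chain of MHC class II and the receptor of MIF, was lower in the ibudilast library in all 6 ranked classes. Its ratio was 0.687 in macrophage-like (interval 0.683 to 0.692), 0.825 in monocyte-like, 0.723 in T-cell-like, 0.841 in NK-cell-like, 0.882 in cDC2-like and 0.651 in cycling cells. The macrophage-like and cycling ratios mix clusters of unlike Cd74 level. Cd74 was at 6552 CPM in cluster 9, against 17249, 18718 and 23878 CPM in clusters 2, 3 and 23. It was at 15617 and 4912 CPM in cycling clusters 10 and 16. In cluster 0 alone the Cd74 ratio was 0.815. In the mixed clusters 5 and 15 the Cd74 level was 11347 and 10840 CPM, against 1392, 3853 and 2858 in the T-cell-like clusters 7, 11 and 14 and 1174 in NK-cell-like cluster 8. Without the mixed clusters the ratio was 0.588 in T-cell-like and 0.538 in NK-cell-like cells, and with the stricter filter it was 0.474 in NK-cell-like cells. Free RNA of other classes was not told apart from Cd74 of the T-cell-like and NK-cell-like cells themselves. In microglia-like cells the Cd74 ratio was 1.41 (interval 1.36 to 1.45). Mif had ratios of 0.927 in macrophage-like, 0.927 in monocyte-like, 0.936 in T-cell-like, 0.760 in NK-cell-like, 0.851 in cDC2-like and 1.02 in cycling cells. In macrophage-like cells it turned to 1.08 in thinned cells and 1.04 with clusters weighted alike, and in cDC2-like cells to 1.20 in thinned cells. Cxcr4, another MIF receptor, had ratios of 1.97 in macrophage-like and 1.42 in NK-cell-like cells.

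Pde4b had ratios of 0.983 in macrophage-like (interval 0.808 to 1.19), 0.895 in monocyte-like, 1.08 in T-cell-like, 1.24 in NK-cell-like (1.0 to 1.55), 0.749 in cDC2-like (0.624 to 0.897) and 1.04 in cycling cells. Pde4d had a ratio of 4.33 in macrophage-like cells, from 60 and 74 UMIs (interval 3.04 to 6.20), and of 2.59 with clusters weighted alike. Its level in PBS cells was 2.09 CPM in macrophage-like and 14.3 CPM in T-cell-like cells, and naive and memory T cell genes were also higher in macrophage-like cells of the ibudilast library (median 1.33, percentile 100). Pde4d had 1.77 in NK-cell-like cells (1.06 to 3.04), from 22 and 55 UMIs. In cycling cells it had 2.03 (1.38 to 3.02), from 48 and 65 UMIs, and 1.14 with clusters weighted alike. When thinned it was at 1.09 in NK-cell-like cells and turned to 0.719 in cycling cells. Thinning to 1000 UMIs per cell, from median cycling depths of 24920.5 and 21418, left few of these UMIs. The thinned Pde4d values therefore show no direction. In monocyte-like, T-cell-like and cDC2-like cells the Pde4d interval held 1. The list of phosphodiesterases named as targets lay within the range of random lists in all 12 cell groups where it could be measured. Only 3 to 5 of its 8 members were measured in a group, so the range was wide. It ran from −0.39 to 0.39 in cDC2-like and −0.57 to 0.59 in microglia-like cells, and differences within it could not be seen. Oxidative phosphorylation genes lay within their range in 12 of 13 groups, the exception being regulatory T-cell-like cells (median −0.16).

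A list was counted as standing above or below random lists only when its interval also excluded 0. Across the 13 cell groups, type I interferon response genes stood above random lists in 9 groups and below in 1. MHC class II genes stood above in 1 and below in 7, and chemokines in 1 and 9. The counts were 1 and 9 for glycolysis and hypoxia genes, and 0 and 8 for pro-inflammatory cytokine genes. These groups overlap, since CD8 and regulatory T-cell-like cells are part of the T-cell-like class. That class and both subsets are among the groups below for MHC class II genes and for chemokines. These cells make little MHC class II, so free RNA stays open there for that list, as do the mixed clusters for the whole class. MHC class II genes lay within the random range in monocyte-like (percentile 3.33), NK-cell-like (12.8), cDC2-like (17.1), cDC1-like (19.7) and B-lineage-like cells (5.85). Markers of killer and T cells stood above in most groups, cytotoxic effectors in 11 and exhaustion and checkpoint genes in 7, macrophage-like cells among them. MHC class I genes stood above in 5 groups, regulatory T cell genes in 5 and cAMP and CREB response genes in 3, and these lists stood below in none. For other lists the groups above and below were 1 and 4 for the MIF axis, 0 and 7 for homeostatic microglia, 1 and 6 for disease-associated microglia, 2 and 4 for immunosuppressive macrophages, and 4 and 4 for the interferon-gamma response. They were 3 and 0 for naive and memory T cells, 3 and 2 for the cell cycle, 3 and 3 for dissociation stress, and 0 and 1 for dendritic cell maturation.

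**Figure D3:**
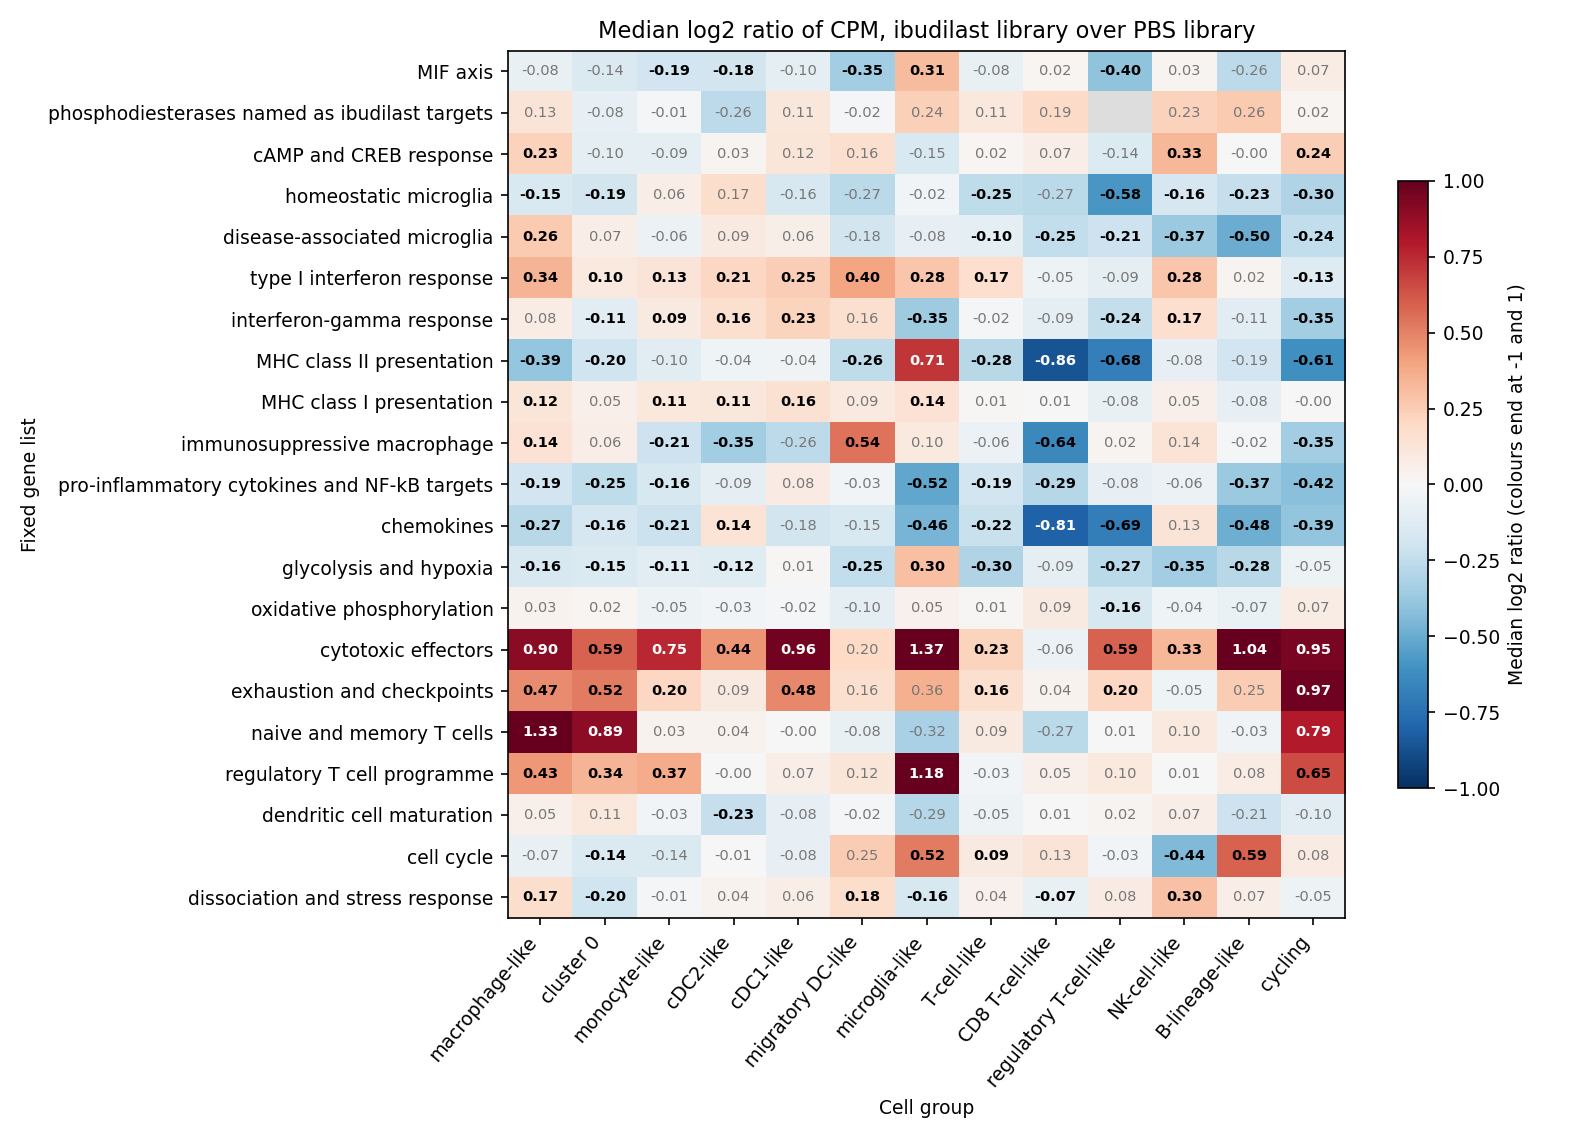
The grid gives the median log2 ratio of ibudilast to PBS for each fixed gene list (vertical) in each cell group (horizontal), on a colour scale in log2 units, in bold where it lies outside the central 95% of matched random lists and its interval excludes 0; grey cells had fewer than 3 members. Type I interferon medians reach 0.40 in migratory dendritic-cell-like cells. MHC class II medians run from −0.86 in CD8 T-cell-like cells, which make little MHC class II, to 0.71 in microglia-like cells.

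On mm10, with GENCODE M21 genes, Mif (ENSMUSG00000033307) lies on chromosome 10 from 75859353 to 75860240 and Cd74 (ENSMUSG00000024610) on chromosome 18 from 60803848 to 60812652. Pde4b (ENSMUSG00000028525) lies on chromosome 4 from 102087543 to 102607259 and Pde4d (ENSMUSG00000021699) on chromosome 13 from 108449948 to 109953461. Mgl2 (ENSMUSG00000040950) spans 70130329 to 70137550 on chromosome 11, Ccl17 (ENSMUSG00000031780) 94810453 to 94812036 on chromosome 8 and Gzmc (ENSMUSG00000079186) 56231441 to 56234656 on chromosome 14. Chil3 (ENSMUSG00000040809) spans 106147554 to 106167564 on chromosome 3 and Ccl5 (ENSMUSG00000035042) 83525778 to 83530518 on chromosome 11. Values count UMIs over the whole gene, so exons were not told apart.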

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

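All tests in this part were chosen after the results were seen, except those of cells lost to the cell filter, of free RNA for ranked genes, whose comparison with the other ranked genes came after, and of the mixed clusters for ranked genes.

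3 measures outside the comparisons were higher in the ibudilast library than in the PBS control. Barcodes at or over the mitochondrial limit were 15.6% against 8.93%. Barcodes under the gene or UMI minimum were 2.31% against 1.06%. Unnamed cluster 21, led by genes such as Col2a1, H19 and Cdkn2a, was 1.68% of kept cells against 0.952%, with median depths of 1058.5 and 15234 UMIs.

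The lower share of macrophage-like cells was set against 3 technical explanations. With barcodes that had enough genes and UMIs but were not kept assigned to their closest cluster, the ratio of macrophage-like shares, cluster 0 included, was 0.467 (interval 0.439 to 0.496), so loss to the filter is argued against. Counting the mixed T and NK clusters as macrophage-like gave 0.645 (0.610 to 0.681). Counting monocyte-like cells in gave 0.763 (0.727 to 0.80), so neither hidden doublets nor the boundary to monocytes accounts for all of it. Differences between mice, tumours or dissections, and an effect of ibudilast, may each underlie it and stay open with 1 library per group.

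Within several classes RNA of another class appeared: of the 25 ranked genes that another class carried at over 5 times the level, 96.0% (24 genes; interval 79.6 to 99.9) differed in the direction of the whole library. So did 88.6% of the other 35 ranked genes, so this measure does not separate free RNA in the droplets from a difference within the class, and both stay open. Some of those 35, such as Mgl2 and Lpl in T-cell-like and NK-cell-like cells, were also higher in another class. For T-cell-like and NK-cell-like genes over the 5-fold limit, the median size of the log2 ratio without mixed clusters was 1.04 times its value. Those clusters therefore do not account for the ratios of these genes. The median UMI count of cluster 5 was 0.968 times the sum of a T-cell-like and a macrophage-like cell in the PBS library (1.15 in the ibudilast library; 1.10 and 1.38 for cluster 15 with NK-cell-like cells), as doublets could give. For haemoglobin RNA, cells with at least 20 such UMIs were left out. The other T clusters were at 11.1 and 82.0 CPM in the PBS and ibudilast libraries, and the other NK cluster at 15.1 and 120.3 CPM. Clusters 5 and 15 were at most at 0.769 times those levels (upper bound 1.37). This argues against free RNA making up more of their UMIs than in the others of the same library. Clusters 5 and 15 were 2.55 to 3.89 times as deep as those others, so the amount of free RNA per cell stays open.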

How the results depend on the processing

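No paired analysis was possible because each group has 1 library. Clustering without the ranked genes, weighting clusters alike, adding cluster 0 and leaving out mixed clusters were chosen after the data were seen. Of 97 ratios of class shares under alternatives, 86 stayed within the interval of the main value, 10 moved and 1 reversed. For T subsets these counts were 11, 1 and 0 of 12. All 17 ratios of cycling shares stayed within theirs. The interval over all kept cells was 0.840 to 1.12. Those of single classes were wide, such as 0.107 to 1.15 in NK-cell-like and 0.475 to 201 in cDC2-like cells, so there the check could hardly fail. Of 620 gene ratios 433 stayed, 183 moved and 4 reversed, and of 1667 list medians 1421 stayed, 227 moved and 19 reversed. Depth limits values of shallow groups such as microglia-like and regulatory T-cell-like cells, with median depths of 4155 and 4262.5 UMIs in the ibudilast library. The values below moved or reversed; the cause was not tested.

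Clustered apart, share ratios were 4.47 for cDC1-like (an ibudilast cluster that Cd209a also led, with none named cDC2-like), 1.14 for monocyte-like, 1.18 for cycling, 0.814 for microglia-like, 0.611 for macrophage-like and 2.51 for non-immune cells. At resolution 0.5 they were 0.819 for microglia-like and 2.95 for non-immune cells, and at 2 the regulatory T-cell-like ratio was 1.07. The macrophage-like ratio was 0.544 with doublets kept and 0.583 without the ranked genes, and the non-immune ratio 1.84 with the stricter filter. Thinned, Mif was at 1.08 in macrophage-like and 1.20 in cDC2-like cells and Pde4d at 0.719 in cycling cells. With clusters weighted alike Mif was at 1.04 in macrophage-like cells.

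With the stricter filter, macrophage-like medians were 0.048 for cAMP response, 0.22 for type I interferon, −0.30 for MHC class II, −0.050 for immunosuppressive and −0.047 for dissociation genes. Monocyte-like medians were 0.22 for type I interferon and −0.25 for chemokines, T-cell-like −0.37 for glycolysis and −0.073 for cell cycle, and NK-cell-like 0.16 for type I interferon and −0.49 for glycolysis. The cDC2-like maturation median was 0.089, and microglia-like ones were 0.020 for interferon-gamma and 0.040 for dissociation. With doublets kept, macrophage-like medians were 0.11 for cAMP response, 0.23 for type I interferon, −0.24 for MHC class II, 0.042 for immunosuppressive genes and −0.33 for chemokines. Type I interferon was at 0.25 in T-cell-like and 0.38 in NK-cell-like cells, NK-cell-like glycolysis at −0.29, the cDC2-like MIF axis at 0.017 and maturation at 0.063, and interferon-gamma at −0.088 in cDC1-like and 0.023 in microglia-like cells.

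With clusters weighted alike, macrophage-like medians were 0.063 for cAMP response, 0.23 for type I interferon, −0.22 for MHC class II, −0.27 for pro-inflammatory and 0.10 for glycolysis genes. T-cell-like ones were −0.0032 for cytotoxic and 0.10 for checkpoint genes, and cycling ones 0.044 for type I interferon, −0.25 for MHC class II and −0.020 for regulatory T cell genes. With cluster 0, macrophage-like medians were 0.075 for cAMP response, 0.23 for type I interferon, −0.29 for MHC class II and 0.042 for immunosuppressive genes. Without mixed clusters, T-cell-like medians were 0.087 for type I interferon and −0.0068 for cell cycle, and NK-cell-like ones 0.33 for homeostatic microglia genes and −0.50 for glycolysis.

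Scaled by TMM, macrophage-like medians were 0.28 for type I interferon, −0.45 for MHC class II and −0.33 for chemokines, and the cycling MHC class II median −0.65. By DESeq2 size factors these were 0.27, −0.45, −0.34 and −0.65. Over members with at least 100 UMIs, chemokine medians were −0.19 in macrophage-like and −0.16 in monocyte-like cells. Microglia-like medians were then −0.13 for cytotoxic and −0.32 for regulatory T cell genes, and that of naive and memory T cell genes in cluster 0 was −0.024.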

Other observations

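The list of IL-4 response genes, and all tests in this part, were chosen after the lower Mgl2 and Ccl17 had been seen. The median was made the deciding value after both it and its percentile were known.

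In microglia-like cells MHC class II genes were higher in the ibudilast library (median log2 ratio 0.71, percentile 100; 6 of 8 members higher), with H2-Ab1 at 1.73, H2-Eb1 at 1.72 and H2-Aa at 1.56. The median was 0.39 with the stricter filter and 0.20 with doublets kept. Genes of other cell types were higher there too: cytotoxic effector genes had a median of 1.37 and regulatory T cell genes of 1.18 (percentile 100 each), which were −0.13 and −0.32 over members with at least 100 UMIs. Pro-inflammatory cytokine and NF-kB target genes were lower (median −0.52, percentile 0; 10 of 13 lower), with Tlr2 at 0.655 and Ccl3 at 0.668, and this median was −0.27 and −0.34 in the same alternatives. Among chemokines Ccl7 was at 0.378 and Ccl2 at 0.399, while Ccl5 was at 1.99. Homeostatic microglia genes had a median of −0.02. Interferon-gamma response genes had a median of −0.35, which turned to 0.02 in both alternatives. These values rest on 267 PBS and 135 ibudilast cells with median depths of 9671 and 4155 UMIs.

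Migratory dendritic-cell-like cells had a type I interferon median of 0.40 (percentile 100; 11 of 17 members higher), with Ifit2 at 2.42 and Ifit3 at 2.22. This median was 0.17 with doublets kept. Ccl17 was at 0.346 there and Ccl22 at 0.698, while Socs2 was at 1.30. In regulatory T-cell-like cells the regulatory T cell programme lay within the range of random lists (median 0.10, percentile 97.4; 4 of 18 members higher and 1 lower), with Il10 at 1.46, Tnfrsf4 at 1.28, Ctla4 at 1.17, Foxp3 at 0.943 and Entpd1 at 0.686. In CD8 T-cell-like cells Gzma was at 0.709 and Gzmb at 0.732, while Ifng was at 1.24 and Tox at 1.58. Cd74 was at 0.482 in CD8 T-cell-like and 0.490 in regulatory T-cell-like cells, which make little MHC class II, so free RNA stays open there.

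A hypothesis links 2 findings. Cluster 26, mast-cell- or basophil-like and led by Mcpt8 and Il4, held 24 PBS and 3 ibudilast cells, with 150 of the 208 Il4 UMIs of the PBS library and 1 of the 60 of the ibudilast library, while Il13 had 19 and 23 UMIs in all. Mgl2 and Ccl17, both induced by IL-4, were lower in cDC2-like cells, and a lower IL-4 signal may connect both findings. The other IL-4 response genes had a median log2 ratio of −0.29 in cDC2-like cells (18 genes, percentile 0). By ratio alone 8 were lower and 0 higher, with Cdh1 at 0.516 and Ccl22 at 0.504. Of the lower genes, Chil3, Pdcd1lg2, Egr2 and Flt1 had intervals that held 1. This median is given for the main setting only. Dendritic cell maturation genes, which share Ccl22 and Pdcd1lg2 with the IL-4 response genes, had a cDC2-like median that turned positive with the stricter filter and with doublets kept. Immunosuppressive macrophage genes, a list that shares Arg1, Chil3 and Mrc1 with the IL-4 response genes, had a median of −0.35 in the same cells (percentile 0). Of the 24 listed genes, 8 also stand in a fixed list and 4 were named by the ranking. The median of the IL-4 response genes was −0.43 in monocyte-like (1 higher, 12 lower) and −0.26 in macrophage-like cells (4 higher, 8 lower). It was −0.11 in cluster 0 (percentile 2.78, 4 higher, 7 lower). In T and NK cells outside the mixed clusters it was −0.11 (percentile 7.63, 3 higher, 6 lower).

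A loss of free RNA could lower a gene in cDC2-like cells by no more than its free level, read here from T and NK cells outside the mixed clusters. Mgl2 was lower by 9.04 times that level of the PBS library and Ccl17 by 215.9 times, so free RNA alone is argued against for this pair of genes. The same multiples were 62.6 for Ccl22 and 4.22 for Cdh1, and under 1.5 for the other IL-4 response genes, for which free RNA stays open. The cluster 26 count is small, and differences between mice stay open.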
